A study of Mus musculus with 16 samples.

How the data were processed

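Total RNA from mouse cells was measured on Illumina BeadChip expression arrays, with 1 array per culture dish and 16 dishes in all. The groups, taken from the cell type in the labels, were embryonic fibroblasts (MEF), the intermediate stage of the induction (OKM), induced pluripotent stem cells (iPS) and embryonic stem cells (ES), with 4 arrays each. Per the labels, MEF, OKM and iPS cells were of strain CD1 and ES cells of strain 129. OKM, iPS and ES cells grew on mitomycin-treated MEF feeders with 15% serum and 10 ng/ml of LIF, and MEF alone with 10% serum.

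The deposited non-normalized table holds, per the file headers, an intensity (mean bead intensity, with background left in) and a detection p-value for each of 25697 probes on each array. The submitters' processing notes name GenomeStudio without a version. The authors also deposited a normalized intensity table on the linear scale. Its columns have nearly the same distribution (medians 24.8 to 25.1), 26.0% of its values are negative and the lowest is -27.3, so a background subtraction is inferred from the values. The rank correlation of each of its columns with its own array in the non-normalized table was at least 0.999998, which was checked against all other arrays (at most 0.968). Per array, the median raw intensity was 114.7 to 134.2 and 44.9% to 49.1% of probes had a detection p-value under 0.01. The number of arrays limits the precision, with a median standard error of 0.13 for a log2 change.

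Probes were paired with gene symbols through the deposited platform annotation, updated by Entrez ID for 23962 probes and by transcript accession for 9 with a RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only. In all, 23978 probes had 1 symbol and 1719 had none. The non-normalized table was processed with limma 3.58.1 in R 4.3.3 (neqc: normexp background correction from the detection p-values, offset 16, quantile normalization, log2). Probes with a detection p-value under 0.01 on at least 4 of the 16 arrays, whatever the group, were kept (13782). A gene with several such probes was represented by the probe with the highest mean over all arrays, which left 9455 genes tested of 16590 on the array.

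Each gene was fitted with a mean per group over all 16 arrays (lmFit, contrasts.fit, eBayes; 12 residual degrees of freedom, 4.84 prior). Tests were two-sided, with Benjamini-Hochberg adjustment over the 9455 genes of a comparison. A gene was called when its adjusted p was under 0.05 and its change at least 2-fold. The 3 main comparisons were OKM vs MEF, iPS vs OKM and iPS vs ES, and the 3 secondary ones ES vs MEF, iPS vs MEF and OKM vs ES. The 27 gene lists with at least 5 measured members, of 30 fixed in advance, were tested with camera (preset correlation 0.01), adjusted over the 81 tests of 27 lists in 3 comparisons. Camera with an estimated correlation and fry were run beside it. The position of an array between the mean MEF and the mean ES profile was its projection on the line that joins them, over all tested genes, and was compared by an exact permutation test. Overlaps of calls were counted beside the number that independent calls would share. Overlaps of comparisons that share a group were recounted with that group's arrays split between them.

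A gene is called detected on an array when its detection p-value is under 0.01. Where a group has 0 detected arrays, its level was set to the lowest level of any detected probe on each of its arrays, and the fold is given as "at least". Genes were named by a rule. It took Pou5f1, Sox2, Klf4 and Myc, and the 10 largest called changes in each direction of each main comparison and 3 of each secondary one, with no overlap between the groups' arrays. It also took up to 3 called members per list and direction, and 5 genes per direction for each step and for the calls that iPS and MEF shared against ES. The text prints part of them. Nanog lies outside the rule and was chosen after its values were seen.

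The procedure was tested on simulated iPS vs OKM data. For each fold 39 to 45 genes were changed, up and down alike, among genes detected on all OKM arrays, with independent errors. The real comparisons change far more genes, so normalization under such wide changes is not tested. Of the genes changed 2-fold, 3-fold and 4-fold, 46.2%, 95.4% and 100% were called, with 0 false calls at both thresholds and 5 at the adjusted p alone. A simulated position of 0.600, made as a mix of the mean MEF and ES profiles with noise, was recovered as 0.601, which checks only the arithmetic. Alternatives covered background correction, normalization, the authors' table, filters, thresholds, the arrays in the fit, a replicate block, array weights, probes per gene, list members and leaving out each array. Fits with the place of an array in the deposited table as a block, fits within each of its parts, a count without the genes that set ES apart, and the recounts with the OKM arrays split and of iPS vs ES with OKM vs ES, were chosen after seeing the data. Probes without a symbol (790 of those kept) were left out of the gene tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Both tests of explanations for the Sox2 signal were chosen after that signal was seen. The groups, comparisons, other tests, lists, naming rule and all other alternatives were chosen before the data were examined.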

Results

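The series follows a stepwise induction of mouse iPS cells with 16 array profiles from 4 groups of 4 dishes. The sample titles mark the OKM cells as 3F, read here as 3 factors, and add Sox2 for the iPS cells. The letters OKM commonly stand for Oct4 (the product of Pou5f1), Klf4 and Myc, which the labels do not spell out. The labels also do not say how the factors were delivered or whether they were still supplied. Where the probes lie in the transcripts was not checked, so an introduced copy and the cell's own gene are not told apart here. Raw medians ran from 114.7 to 134.2 and 44.9% to 49.1% of probes were detected per array. The p-values reflect the spread between dishes, and the labels call the dishes independent without saying what separated them.

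Arrays resembled those of their own group most. Pearson's r across genes was 0.984 to 0.996 within groups. It averaged 0.828 between MEF and OKM, 0.937 between OKM and iPS and 0.920 between iPS and ES (genes are not independent replicates). On the axis from the mean MEF profile (0) to the mean ES profile (1), OKM lay at 0.529 ± 0.0038 and iPS at 0.727 ± 0.0131 (SD, n = 4). MEF and ES also differ in strain, line and culture, which are part of this axis, so a position is not a measure of induction alone. The difference of 0.198 gave an exact two-sided permutation p = 0.0286, the smallest that 70 splits allow. Deviations from the group means also split the arrays by their place in the deposited table. Its first 8 and last 8 arrays, each with 2 arrays of every group, lay on opposite sides of the first component of these deviations (25.8% of their variance). This split was noticed in the deviations and then matched to the column order. The iPS to OKM difference was 0.189 in the first 8 arrays and 0.206 in the last 8.

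**Figure D1:**
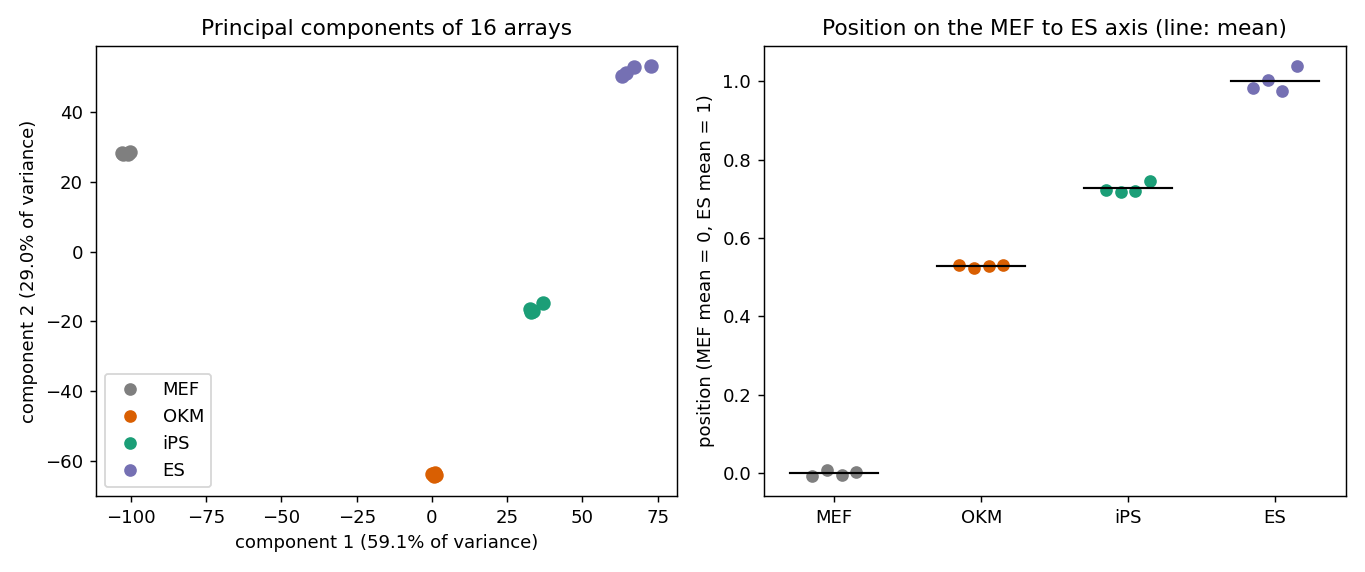
Left, scores of the 16 arrays on the first principal components of the normalized log2 intensities, coloured by group. Right, position of each array between the mean MEF profile (0) and the mean ES profile (1), with a line at each group mean; OKM arrays lie near 0.529 and iPS arrays near 0.727.

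OKM vs MEF asks what changed in the first step, from fibroblasts to the intermediate stage. Culture changed with the step. OKM cells grew on feeders with 15% serum and LIF, and MEF alone with 10% serum, so step, culture and feeder RNA cannot be separated here. Pou5f1, the central transcription factor of pluripotency, was at background in MEF and reached a log2 intensity of 11.59 ± 0.05 in OKM (SD, n = 4), at least 57.0-fold higher. The bound sets the undetected group at the dimmest detected probe of its own arrays. Sox2, its partner factor, also rose from background to 10.12 ± 0.16, at least 20.6-fold higher, in the stage whose titles do not yet name it. That rise rests on a single probe, since the second Sox2 probe was detected on 0 of 4 OKM arrays and was not kept. Klf4 moved the other way, from 8.86 ± 0.18 in MEF to below detection on all 4 OKM arrays, at least 9.22-fold lower, and its 3 probes fell alike. Esrrb and Nanog, core members of the pluripotency network, stayed near background in OKM, with detection on 0 and 1 of 4 arrays.

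Among the largest rises were those of Mzb1, an endoplasmic reticulum protein best known from B cells (at least 654-fold), and the amino acid transporter gene Slc38a5 (at least 454-fold). Klk1b27, Klk1b5 and Klk1 rose at least 337-fold, 168-fold and 140-fold. These kallikrein genes are so alike that their probes may not separate them. Urah, the bHLH factor gene Msc, Wfdc2, Scg5 and Nccrp1 each rose at least 86.5-fold. The growth factor gene Ptn fell by 8.87 on the log2 scale, elastin (Eln) was at least 105-fold lower, and Lgr5, a receptor gene tied to Wnt signalling, at least 89.6-fold lower. Ogn fell by 7.36 (detected on 2 of 4 OKM arrays), Lpl by 6.94, Cxcl12 by 6.84 and Mfap4 by 6.59, and Ecrg4, C1qtnf3 and Ldb2 ended below detection. Myc fell by 1.09 (adjusted p = 0.000127). Without OKM replicate 2 the change was -0.96 and no longer called, as with 3 alternatives for the background and the table used (-0.58 to -0.84).

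By list, 35 of 40 fibroblast and mesenchymal genes fell and 1 rose (Cd44), with Lum, Thbs1 and Col3a1 falling by 5.42, 5.36 and 4.53 (list adjusted p = 7.85e-11; adjusted p = 0.216 with an estimated correlation). Of 26 TGF-beta responsive genes 18 fell, among them Tagln and Col1a1, and 2 rose, Id1 and Skil (adjusted p = 0.000604; adjusted p = 0.216 with an estimated correlation). Epithelial genes rose in 15 of 28 cases, led by the splicing regulator Esrp1 and by Elf3, at least 25.3-fold and 12.3-fold, and Krt19 (1.32e-05; 0.0221 with an estimated correlation). Of 26 ES cell associated genes 19 rose, including Upp1 by 7.11 (detected on 1 of 4 MEF arrays), Fbxo15 at least 77.0-fold and L1td1 at least 41.4-fold (7.87e-07; 0.00143 with an estimated correlation). Core pluripotency regulators were mixed, with 7 of 16 higher (Pou5f1, Sall4 and Sox2 the most) and Klf4 and Klf2 lower. That list's adjusted p of 0.0195 was lost with an estimated correlation (adjusted p = 0.296) and without members that other lists share (adjusted p = 0.109).

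Of 32 DNA replication genes 20 rose, with Mcm10, Cdc45 and Pold2 up by 2.58, 2.12 and 1.92 (adjusted p = 6.49e-08; adjusted p = 0.000793 with an estimated correlation), and 14 of 23 mitotic genes rose, with Nusap1 up by 2.10 (2.03e-06; 0.00221 with an estimated correlation). Of 24 DNA methylation and Polycomb genes 9 rose, Cbx7, Phc1 and Uhrf1 the most, and 1 fell (0.0117; 0.0470 with an estimated correlation). Glycolysis genes rose in 11 of 21 cases, with the glucose transporter gene Slc2a3 up by 3.40, Aldoc by 3.12 and Hk2 by 2.19 (9.81e-05; adjusted p = 0.131 with an estimated correlation). The ribosomal protein list shifted up although only Rpl22 of 37 was called (adjusted p = 0.00530; adjusted p = 0.151 with an estimated correlation). With cyclic loess in place of quantile normalization both calls ended (list adjusted p = 0.186, Rpl22 at 0.80), and the call of Rpl22 also with median scaling (0.92).

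Markers of other cell types moved too. Of 14 blood and immune cell markers 10 were lower in OKM, with the macrophage complement genes C1qb and C1qc at least 33.3-fold and 34.3-fold lower, while 2 were higher, Hba-a1 the most (adjusted p = 0.000442; adjusted p = 0.0873 with an estimated correlation). Of 11 fat, cartilage and bone markers 8 fell, including Lpl and Pparg, and 2 rose (adjusted p = 0.0203; adjusted p = 0.0932 with an estimated correlation). The other 15 lists tested did not shift against the remaining genes.

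In all, 1522 genes rose and 1490 fell between MEF and OKM, 290 and 239 of them at least 8-fold. Within the first 8 and the last 8 arrays alone, 2980 and 3077 genes were called, and 3012 with the place in the table as a block. Of 27 lists 12 shifted (8 up, 4 down; 5 with an estimated correlation; 12 in each part of the table). As many shifted in 7 of the 35 splits of these arrays, the real one included. The others all kept 3 arrays of a group together, and splits that kept 2 together shifted at most 1. By fry, which tests a list by itself and not against the other genes, 26, 18 and 24 of the 27 lists passed in OKM vs MEF, iPS vs OKM and iPS vs ES. In every list and comparison the numbers of called members were the same when adjusted over the list alone.

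**Figure D2:**
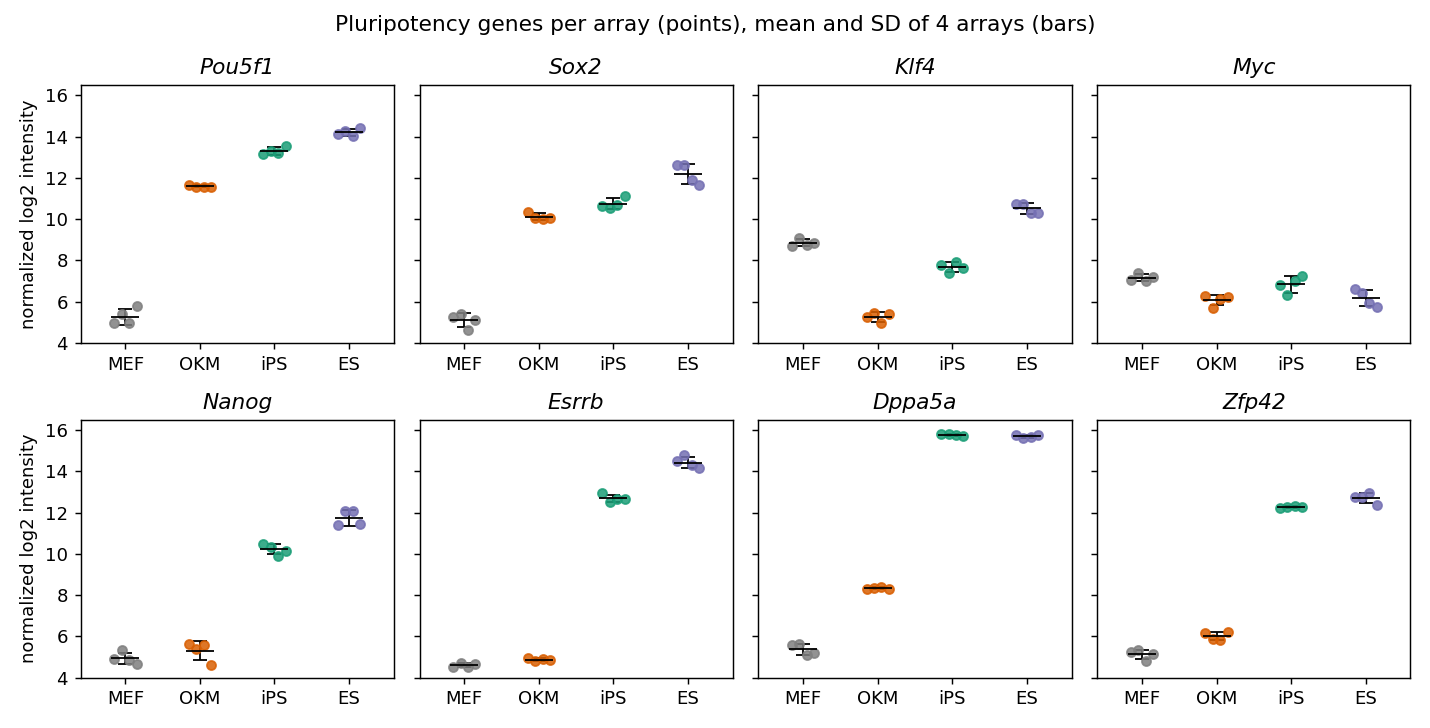
Normalized log2 intensity of 8 genes on each of the 16 arrays (points, 4 per group), with the mean and SD of each group (bars). Pou5f1 and Sox2 are high in OKM at 11.59 and 10.12, Klf4 is lowest in OKM at 5.26, and Nanog, Esrrb, Dppa5a and Zfp42 reach 10.22 to 15.76 in iPS.

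iPS vs OKM asks what the second step, with Sox2 named in the titles, added. Several genes of the pluripotency network that were absent or low in OKM reached high levels in iPS. Esrrb, a nuclear receptor of that network, went from below detection to 12.68 ± 0.18 (SD, n = 4), at least 131-fold, and Zfp42 (Rex1) rose by 6.27 to 12.28 ± 0.06. Dppa5a, already at 8.33 in OKM, rose by 7.43 to a raw intensity among the 11 highest of each iPS array, where a probe may saturate. Nanog, named after its values were seen, rose by 4.92 to 10.22 ± 0.25 (adjusted p = 5.06e-12). Dnmt3l, a cofactor of new DNA methylation detected on 3 of 4 OKM arrays, rose by 8.87 (SE 0.15).

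Utf1 and Lefty1, an inhibitor of Nodal signalling, rose at least 57.6-fold and 55.0-fold, the tight junction gene Cldn6 and Pla2g1b at least 79.5-fold and 77.7-fold, and Ooep and Dppa4 by 7.03 and 6.71. Pou5f1 rose further, by 1.71, and Klf4 returned from background to 7.68 ± 0.24, at least 4.08-fold higher. Sox2 and Myc passed the adjusted p alone (0.0201 and 0.00462), with changes of 0.62 and 0.75 below the 2-fold threshold. Among the deepest falls were those of the kallikreins that had risen in the first step, Klk1b27 at -6.33, Klk1b5 at -6.26 and Klk1 at -6.12. Spns3, Art3 and Cd3g fell below detection, at least 11.7-fold, 10.3-fold and 8.08-fold lower, and Olfml1 and Cyp2b23 changed by -3.67 and -3.64.

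By list, 13 of 16 core pluripotency regulators rose and 0 fell (adjusted p = 1.74e-12; adjusted p = 0.0110 with an estimated correlation), and 18 of 26 ES cell associated genes rose and Pim2 fell (3.23e-10; 0.000521 with an estimated correlation). Of 28 epithelial genes 11 rose, with Ap1m2 and Grhl2 at least 10.1-fold and 9.06-fold higher, while Grhl3 and Krt19, higher in OKM than in MEF, fell (7.12e-05; 0.0298 with an estimated correlation). Of 12 primed epiblast genes 8 rose, among them Dnmt3b by 4.35, Pou3f1 by 3.18 and Fgf5 at least 2.73-fold, and Zic2 fell, a call that ended without background correction (-0.61) and in 2 other settings (0.000635; 0.0175 with an estimated correlation). Of 12 germline genes 7 rose, with Tex19.1 up by 3.74 and Tex14 at least 3.48-fold (4.50e-06; 0.0289 with an estimated correlation). The trophoblast list rose in 9 of 18 cases, led by the homeobox genes Rhox9 and Rhox6, up by 4.37 and 3.64 (Rhox6 was detected on 1 of 4 OKM arrays), and Tfap2a fell (3.09e-05; 0.0314 with an estimated correlation).

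Among chromatin genes, 3 of 28 histone and chromatin modifiers rose, with Arid3b up by 2.82 and Trim28 by 1.09 (adjusted p = 0.000707; adjusted p = 0.0166 with an estimated correlation). Of 24 DNA methylation and Polycomb genes 6 rose and 2 fell (0.0331). That call was lost with an estimated correlation (adjusted p = 0.0873), with the replicate block (adjusted p = 0.0631) and without members shared with other lists (adjusted p = 0.391). The DNA replication list shifted up with 2 of 32 members called, Mcm2 and Ccne1 (0.00350; 0.0221 with an estimated correlation).

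Of 25 Hox genes 4 fell, with Hoxb6, Hoxb5 and Hoxc6 down by 2.11, 1.91 and 1.47 (adjusted p = 0.00379; adjusted p = 0.151 with an estimated correlation). Of 31 interferon response genes 6 fell, with Rsad2 and Oas2, both higher in OKM than in MEF, at -2.73 and -1.81 (adjusted p = 0.00673; adjusted p = 0.254 with an estimated correlation). Of 24 p53 and senescence genes 3 fell, among them the cell cycle inhibitor gene Cdkn1a at -1.14 and Sesn1 at -1.18. That list's adjusted p of 0.0443 rose to 0.0651 without OKM replicate 3 and 0.0510 without iPS replicate 3 (adjusted p = 0.109 with an estimated correlation). Fibroblast genes, with 6 of 40 lower, missed the test (adjusted p = 0.0683; adjusted p = 0.702 with an estimated correlation) but passed in 4 alternatives (0.0197 to 0.0479), without OKM replicate 4 (0.0442) among them. TGF-beta responsive genes, with 6 of 26 lower and 1 higher, missed it (0.0532; adjusted p = 0.463 with an estimated correlation) but passed in 8 alternatives (0.0280 to 0.0472), without OKM replicate 4 (0.0393) and with the replicate block (0.0302) among them.

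In all, 688 genes rose and 562 fell in the second step, against 3012 called in the first. Within the first 8 and the last 8 arrays 1234 and 1354 genes were called, and 1251 with the place in the table as a block. Of 27 lists 12 shifted (9 up, 3 down; 8 with an estimated correlation; 11 and 13 within the parts of the table). As many shifted in 6 of 35 splits, the real one included. The others kept 3 arrays of a group together, and splits that kept 2 together shifted at most 3.

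ES vs MEF gives the full distance from fibroblasts to ES cells, with differences of strain, line and culture included. For part of its genes the 2 steps show where they moved. Culture also differs between iPS and MEF. Dppa5a, Esrrb and Trh, the thyrotropin-releasing hormone gene, were at least 987-fold, 407-fold and 320-fold higher in ES, and Ptn fell by 9.45, Ogn and Lgr5 at least 149-fold and 88.9-fold lower. Dppa5a, Trh, Dppa4, Upp1 and Pou5f1 are the largest of the genes higher in ES that had risen in the first step, and Ptn, Ogn, Lgr5, Mylk and Igfbp5 of those that had fallen. Esrrb, Lefty1, Dnmt3l, Zfp42 and Utf1 were called higher in the second step and not in the first, and Actg2, Tnfrsf11b, Scara3, Fos and Sh3bgrl lower. A missed call is not the absence of a change, since Zfp42 was detected on 0 of 4 MEF arrays and all 4 OKM arrays (at least 1.19-fold higher) and Sh3bgrl just missed the 2-fold threshold (adjusted p = 0.00238).

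Of the 2286 genes higher in ES than in MEF, 681 were called higher in the first step and not called in the second. Another 338 were called higher in the second and not called in the first, 106 were higher in both and 1048 were called in neither. A further 82 rose in the first step and fell in the second, 23 fell and then rose, and the rest moved only away from ES. Of the 2299 lower in ES, 1059 were called lower in the first step and not called in the second. Another 129 were called lower in the second and not called in the first, 53 were lower in both and 915 were called in neither. A further 53 fell in the first step and rose in the second, 39 rose and then fell, and the rest moved only away from ES. The first step shared 2034 calls in direction with ES vs MEF (730.3 for independent calls) and 115 went the opposite way. With the MEF arrays split between the comparisons it shared 2001. The second step shared 688 (303.0 for independent calls) and 142 were opposite. Within the first 8 and last 8 arrays the shared calls were 2003 and 2077 for the first step and 661 and 752 for the second. Of the 1522 genes that rose in the first step 329 fell again in the second, as the kallikreins did (90.5 for independent calls), and of the 1490 that fell 147 rose again (108.4). With the OKM arrays split between the steps, a recount chosen after seeing the data, these were 335 and 142 (91.2 and 106.8). iPS vs MEF called 1798 genes up and 1654 down (3392 and 3553 in all within the parts of the table), with Dppa5a, Mzb1 and Dppa4 at least 1030-fold, 520-fold and 238-fold higher. ES vs MEF called 4560 and 4582 genes within those parts. With Klf4 at -1.18 (-0.92, not called, without background correction) and Myc not called (-0.33), iPS kept Pou5f1 at least 187-fold and Sox2 at least 31.6-fold above MEF.

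**Figure D3:**
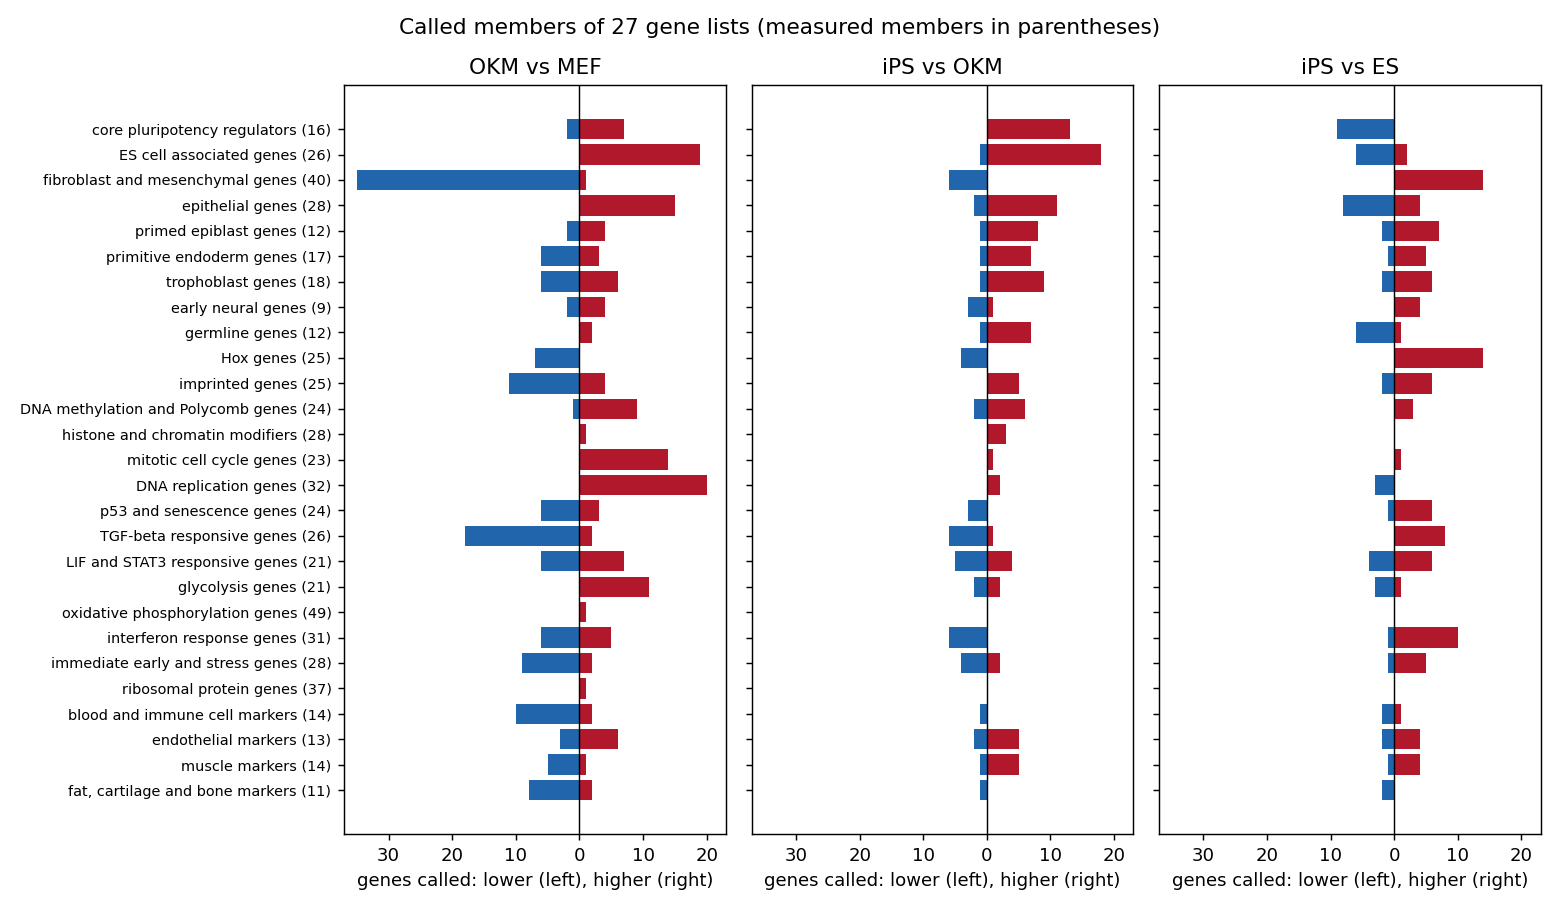
Numbers of members of 27 gene lists called lower (blue, left) and higher (red, right) in the 3 main comparisons, with the number of measured members in parentheses. Fibroblast genes lead the falls of the first step with 35 of 40, and 13 of 16 core pluripotency regulators rose in the second.

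iPS vs ES asks how far the induced cells still differed from ES cells. Core pluripotency regulators were lower in iPS in 9 of 16 cases and higher in 0, with Klf4 at -2.83, Nr5a2 at -2.21, Tcl1 at -2.18 and Sox2 at -1.45 (list adjusted p = 5.22e-06; adjusted p = 0.0664 with an estimated correlation). Esrrb reached 12.68 ± 0.18 in iPS and 14.43 ± 0.27 in ES, and Nanog 10.22 ± 0.25 and 11.75 ± 0.39 (SD, n = 4). Pou5f1 was 0.90 lower on the log2 scale in iPS, short of the 2-fold threshold, which median scaling in place of quantile normalization passed (-1.04). All ES cells were of strain 129 and all iPS cells of CD1, so strain, cell line and state cannot be separated in any comparison with ES.

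Tph1, the enzyme gene of serotonin synthesis, and the claudin gene Cldn11 were at least 91.9-fold and 100-fold higher in iPS. Mzb1 and the keratin gene Krt14 were higher by 8.41 and 7.01, and Scg5, Csprs, Lgals7, Icam2 and Avil at least 32.7-fold. Csprs belongs to a repeated family that its probe may not resolve. Plk1, the mitotic kinase gene, was 6.16 higher in iPS, on a single probe that was detected on 3 of 4 ES arrays. Cbwd1, Ttc27, Wdr46 and Apoa2 were at least 24.3-fold, 32.0-fold, 24.5-fold and 21.5-fold lower in iPS, and Olig1, detected on 1 of 4 iPS arrays, was at -4.58. Aqr was at least 9.23-fold lower by its brightest probe and at -0.71, not called, by its other probe. Hal, Tmem68, Crtac1 and Myo1f were at least 7.84-fold lower. Of these 10 lowest genes 7 lay far from ES in all 3 CD1 groups alike.

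Hox genes were higher in iPS in 14 of 25 cases and lower in 0, with Hoxd9 and Hoxd8 at least 6.12-fold and 4.35-fold higher and Hoxb2, detected on 2 of 4 ES arrays, at 2.61 (adjusted p = 1.92e-06; adjusted p = 0.0289 with an estimated correlation). Fibroblast and mesenchymal genes were higher in 14 of 40 cases and lower in 0, with Timp3 at 3.83, Cd44 at 2.96 and Axl at 2.27 (adjusted p = 2.38e-06; adjusted p = 0.367 with an estimated correlation). TGF-beta responsive genes were higher in 8 of 26 cases, including the receptor gene Tgfbr2 at 3.38 and Ltbp1 at 2.16 (0.00115; adjusted p = 0.221 with an estimated correlation). Of 24 p53 and senescence genes 6 were higher, Fas at 2.77 and Cdkn2a at 1.62 among them, and 1 was lower (0.0188; adjusted p = 0.0664 with an estimated correlation). Interferon response genes were higher in 10 of 31 cases, with Gbp2 at 2.33 and H2-K1 at 1.90, and Ifitm1 lower (adjusted p = 0.0262; adjusted p = 0.352 with an estimated correlation). The DNA replication list shifted down with 3 of 32 members called, Pold2 at -1.26 the most (9.91e-05; 0.00589 with an estimated correlation).

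Lineage lists shifted as well. Of 12 primed epiblast genes 7 were higher in iPS, Fgf5 at least 2.71-fold and Pou3f1 at 1.83, and Igfbp2 and Fgf15 lower, the latter not without background correction (-0.76) or with offset 50 (-0.97) (adjusted p = 0.0337; adjusted p = 0.0920 with an estimated correlation). Of 17 primitive endoderm genes 5 were higher, with Srgn at least 10.0-fold and Dab2 at 2.47, and Lama1 lower at -2.73 (0.0290; adjusted p = 0.175 with an estimated correlation). Of 9 early neural genes 4 were higher, Zic1 at least 3.46-fold (0.0164; adjusted p = 0.0692 with an estimated correlation; 0.133 with no filter on dim probes). Of 12 germline genes 6 were lower, with Tex14 and Stag3 at -2.10 and -2.06, and Piwil2 higher (0.0443; adjusted p = 0.275 with an estimated correlation). Glycolysis genes shifted down with 3 of 21 lower, Aldoc at -1.53, and Eno2 higher (0.0443; adjusted p = 0.426 with an estimated correlation), and oxidative phosphorylation genes with 0 of 49 called (0.0309; adjusted p = 0.367 with an estimated correlation).

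Several of these list calls depended on single dishes or settings. Without iPS replicate 4 the adjusted p was 0.0537 for primed epiblast and 0.0597 for germline genes, and without ES replicate 5 it was 0.0612 for interferon response and 0.0798 for glycolysis genes. Without iPS replicate 1 or 3 it was 0.0567 and 0.0510 for glycolysis genes and 0.0711 and 0.0510 for oxidative phosphorylation genes, which without ES replicate 4 had 0.0621. The germline call also ended with 6 other settings, the place in the table as a block among them (adjusted p = 0.0615). With the replicate block the adjusted p was 0.0724 for glycolysis and 0.0631 for interferon response genes. That block takes ES replicate 5 out of iPS vs ES, since no other dish has its number. It is thus not a check apart from leaving that dish out. With the mean of a gene's probes the adjusted p was 0.0680 for oxidative phosphorylation genes. Without members shared with other lists it was 0.116 for primed epiblast and 0.0822 for glycolysis genes.

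In all, 1061 genes were higher and 688 lower in iPS than in ES. Of the 1061, 898 were also higher in OKM than in ES, 671 in MEF than in ES and 590 in both. Of the 688 lower, 566, 546 and 465 were shared in the same way. With the ES arrays split, also chosen after seeing the data, iPS vs ES shared 1439 calls with OKM vs ES (1464 unsplit, 304.7 for independent calls). The calls shared with MEF vs ES numbered 1217 (424.3 for independent calls; 1204 with the ES arrays split; 1339 and 1136 within the first and last 8 arrays), with Cldn11, Krt14, Plk1, Hs3st3a1 and Ly6c1 the highest. Within the first 8 and last 8 arrays 1924 and 1669 genes were called, and 1749 with the place in the table as a block. Of 27 lists 13 shifted (8 up, 5 down; 2 with an estimated correlation; 11 within each part of the table and 12 with the block). As many shifted in 4 of 35 splits, the real one included. The others kept 3 arrays of a group together, and splits that kept 2 together shifted at most 5. OKM vs ES, farther apart, called 1704 genes up and 1559 down (3302 and 3249 in all within the parts of the table), with Cldn11 at least 391-fold higher and Esrrb and Lefty1 at least 437-fold and 192-fold lower in OKM.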

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

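The tests of both explanations for the Sox2 signal were chosen only after the result was seen. The other tests in this part were set before their results.

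Sox2 was detected on all 4 OKM arrays, in cells whose titles do not name it, at 58.8% to 75.3% of its iPS level above MEF. If iPS or ES cells had been mixed into the OKM dishes, their other transcripts would have come with Sox2. The 12 other core pluripotency genes called higher in iPS than in MEF reached a median of 6.07% of their iPS level (2.88% to 8.90% by dish). By gene the share ran from -78.8% (Klf2) to 72.0% (Klf5), and Klf5 alone passed the mean of Sox2 (63.8%). Against the ES level, 13 such genes reached a median of 0.522% and Sox2 20.7% to 26.5% by dish. These medians argue against mixed cells as the whole cause. Cross-hybridisation of the single informative probe cannot be told apart from a Sox2 transcript. The second Sox2 probe was above background on 0 of 4 OKM arrays, but also on 0 of 4 iPS and only 1 of 4 ES arrays. Its mean log2 intensity was 4.59 in MEF and 4.51 in OKM, against 5.07 in iPS and 5.32 in ES. It thus did not rise in OKM, but a probe this near background cannot decide. A biological explanation, early expression of Sox2 in the OKM stage, may hold and was not tested.

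In 16 genes all 3 CD1 groups lay at least 8-fold to the same side of ES and within 2-fold of each other, 10 lower and 6 higher than ES, among them Cbwd1, Wdr46, Apoa2, Plk1 and the Y-linked gene Eif2s3y. These folds use the normalized levels as they are, undetected probes included. With undetected groups set at the floor some fall short of 8-fold, Eif2s3y among them. Closeness of undetected CD1 groups is closeness at background. A strain variant under a probe could produce this. It would leave a second probe of the same gene unchanged, but only 4 of the genes had one that passed, and 75% of these were called the same way, too few to decide. Among the 1039 other genes called to the same side of ES in all CD1 groups, 63.5% of 373 second probes were called the same way. In the same-strain comparison iPS vs OKM it was 67.7% of 362 (Fisher's exact p = 0.245), which does not decide either. The same-strain comparison OKM vs MEF had 78% of 1057, and the 694 other iPS vs ES calls 56.1% of 205. Both differ from iPS vs OKM (Fisher's exact p = 0.000131 and 0.00652), so the outcome depends on the comparison taken as reference. Strain, sex and line of the cells stay open and untested.

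Of the genes higher in iPS than in ES, 671 were also higher in MEF than in ES. More feeder fibroblast RNA in the iPS dishes might do this, but fibroblast markers would then be raised by as large a share. The 671 genes needed a median 45.1% of the MEF level, while the median of the 40 fibroblast markers allowed 5.78% (95th percentile of resampled medians 10.98%). The 671 were picked as called higher in iPS than in ES, which raises their share, and the markers only as lower in ES. Single markers ran from -3.09% (Meox1) to 150.4%, and 82 of the 671 genes lay above that. The typical marker was raised by a small share only. For the typical gene of the 671, the medians argue against feeder RNA like that of the MEF arrays as the whole cause. A smaller share of feeder RNA, or feeders unlike the MEF arrays, is not excluded. Expression kept from the fibroblast state and the difference between strains stay open, as untested explanations.

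For the number of called genes the real grouping gave more than any other split in all 6 comparisons. Only 1 of 35 splits of the arrays, the real one, gave as many, and the highest other was 36 genes in iPS vs ES (1749 real) and 0 in the other 5. A share of 1 in 35 is the smallest that the splits allow. The other splits mix arrays of 2 groups that differ, which widens the spread, so their low counts do not measure what chance gives. Anything else that the dishes of a group shared is not tested. For the number of shifted lists the splits do not decide, and chance is not excluded. In OKM vs MEF 7 of 35 splits gave 12 or more (highest other 13), in iPS vs OKM 6 gave 12 or more (highest other 13) and in iPS vs ES 4 gave 13 or more (highest other 14). Each split also regroups arrays of the other comparisons, over which the lists are adjusted, so that the real iPS vs OKM split shifted 13 lists there, and 3 splits gave 13 or more. Apart from the real split, those that gave as many all kept 3 arrays of a group together and so still carried part of the group difference. Splits that kept 2 together shifted at most 1, 3 and 5 lists. The split by place in the deposited table shifted 0, 1 and 4 lists.

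Of 44 tests for a sample far from the others of its group, 4 found one, where chance gives about 1 in 20. Sox2 was 10.36 in OKM replicate 1 and 10.01 to 10.07 in the others. The raw median of iPS replicate 2 was 122.8 against 132.9 to 134.2. The position of iPS replicate 4 was 0.746 against 0.718 to 0.722. In ES replicate 2, 48.99% of probes were detected against 45.82% to 46.10%. Probes with no gene symbol, which the comparisons do not use, also held signal, and 264 of 790 were called in OKM vs MEF, 102 in iPS vs OKM and 164 in iPS vs ES.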

How the results depend on the processing

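The fits that use the place of an array in the deposited table, and the count without genes that set ES apart, were chosen only after the result was seen. Counts of called genes stayed within 1.5 times the reported ones in 92 of 103 values from alternatives other than leaving out a dish. Without background correction they were 1980 (OKM vs MEF), 674 (iPS vs OKM), 939 (iPS vs ES), 2274 (iPS vs MEF) and 2131 (OKM vs ES), since background left in shrinks the folds of dim genes. Calls shared with ES vs MEF were then 1295 for OKM vs MEF and 380 for iPS vs OKM, and iPS vs ES shared 596 with MEF vs ES. Signal over background limits what can be called. With the adjusted p alone, which drops the fold threshold, they were 6668, 5182, 5851, 7725, 7210 and 6987. Lists shifted with an estimated correlation numbered 5 in OKM vs MEF and 2 in iPS vs ES. That correlation was 0.492 for fibroblast genes and 0.162 for core pluripotency and TGF-beta responsive genes, far above the preset 0.01, which weakens a list's test. Calls also ended for lists estimated below 0.01, such as p53 and senescence genes in iPS vs ES (0.00484), for a cause that was not tested. With the replicate block, which pairs dishes by their number, 3012, 1251 and 1675 genes were called in the main comparisons. ES replicate 5 shares its number with no other dish, so the block takes it out of the comparisons with ES. However, r between the deviations of dishes with the same number was -0.42 to 0.55 and over 0.1 in only 4 of 21 pairs. Of these, 3 were MEF with OKM, where same-numbered dishes also lie in the same part of the table. A slide block was not run, since no slide is named. Without the 16 genes that set ES apart, all of them called, the iPS vs ES count is 1733 by construction, which tests nothing. The position difference was 0.1888 and 0.2059 within the first and last 8 arrays, where p = 0.333 is the smallest an exact permutation test of 2 against 2 can give. Leaving out each dish in turn gave 2995 to 3030 called genes in OKM vs MEF, 1243 to 1275 in iPS vs OKM, 1687 to 1846 in iPS vs ES, 4567 to 4616 in ES vs MEF, 3394 to 3495 in iPS vs MEF and 3237 to 3306 in OKM vs ES. It gave 12 to 12, 11 to 14 and 11 to 13 shifted lists in OKM vs MEF, iPS vs OKM and iPS vs ES. Calls shared with ES vs MEF were 2020 to 2053 for OKM vs MEF and 682 to 714 for iPS vs OKM. Those of iPS vs ES with MEF vs ES were 1160 to 1307, and position differences were 0.1913 to 0.2032. Single genes were run in part of the alternatives only. These were background correction, offset, normalization, the authors' table, the replicate block, the mean of a gene's probes, the place in the table as a block and each dish left out. Of 402 values of single genes, 337 kept direction and call in every one of these and 63 lost or gained a call in at least 1. The uncalled values of 2 turned. Gm428 in iPS vs ES was 0.06 with the replicate block and -0.28 to 0.10 when each dish was left out, with 0.10 without ES replicate 5. Myc in OKM vs ES was -0.24 to 0.04, with 0.03 without OKM replicate 2 and 0.04 without ES replicate 1. The cause was not tested.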

Other observations

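The tests of the lists below were set before the data were examined and none was chosen after its result. Several imprinted genes changed without a shift of their list against the other genes by camera. In OKM vs MEF 4 of 25 rose and 11 fell, with Phlda2 at least 6.41-fold higher, Ddc up by 3.58 and Snrpn by 2.59, and Mest at least 20.5-fold lower, Dlk1 at -5.19 (detected on 1 of 4 OKM arrays) and Igf2 at -3.44 (adjusted p = 0.154). Phlda2 rose again in iPS, by 4.11. Against ES, Igf2 was at 2.64 and Nnat at least 2.76-fold lower (-0.95, not called, without background correction), with 6 higher and 2 lower (adjusted p = 0.514). Endothelial markers rose in 6 of 13 cases and fell in 3 in the first step, with Pecam1 and Icam2, cell adhesion genes, at least 32.4-fold and 19.4-fold higher (adjusted p = 0.391). Icam2 was at least 32.7-fold higher in iPS than in ES, while Pecam1 fell by 1.08 from OKM to iPS.

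Genes that answer to LIF went both ways at each step. In OKM vs MEF, where the labels name LIF for OKM alone, 7 of 21 were higher and 6 lower (adjusted p = 0.241). Pim3, Klf5 and Bcl3 rose by 3.33, 3.00 and 2.68 while Socs2 fell by 1.54, and Socs2 returned in iPS by 2.07 while Socs3 fell by 1.12. Of 28 immediate early and stress genes 9 fell and 2 rose in the first step (adjusted p = 0.241), with Chac1 and Ddit3, targets of the integrated stress response, down by 3.27 and 3.24. Chac1 rose again in the second step by 2.69. Among muscle markers, 1 of 14 rose and 5 fell in the first step (adjusted p = 0.236). Nppb was 4.77 higher in iPS than in ES. Of the lists with too few measured members for a test, the 2-cell stage genes Zscan4c and Gm428 were at least 7.53-fold and 2.02-fold higher in iPS than in OKM, on probes that may not separate members of their families, though without background correction Gm428 stood at 0.92 and was not called. Among sex chromosome genes, Eif2s3y was detected on all 4 ES arrays and on 0 of the CD1 arrays, and at least 5.29-fold lower in iPS than in ES. The others went differently, and do not settle the sex of the cells. The Y-linked gene Uty was detected on 3, 1, 2 and 2 of 4 arrays of MEF, OKM, iPS and ES and Kdm5d, also Y-linked, on 1, 2, 1 and 0, while Xist was detected on all 4 MEF arrays and on 0 of the others.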
